A study of Mus musculus with 12 samples.

How the data were processed

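Total RNA from colonic epithelium of 12 mice was sequenced, 4 mice in each of 3 groups, and each library was used as 1 sample. Per the file headers, the deposited values are counts of reads per gene symbol, made by the authors with featureCounts 1.6.1 (Subread) over the exons of Ensembl GRCm38 release 98. The strand setting was 0, so reads were counted without regard to strand, and reads that mapped to several places or fell in more than 1 gene were left out. The authors aligned the reads with STAR, whose version is not given in the sources used here. The files hold 55304 gene symbols, of which 53569 were matched to an Ensembl identifier and 8 lie on more than 1 chromosome, and 41205 had a count in some library. Close gene families, such as Ceacam genes, glutathione transferases, mast cell proteases and alkaline phosphatases, are measured by their uniquely mapped reads alone.

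Groups were taken from the labels. Sex was read from Xist and Y-linked genes and checked across all 12 libraries. Library totals were 7421411 to 10344161 with a median of 8138352, and the common biological coefficient of variation was 18.3%. Intervals for shares of counts are 95% Wilson intervals, and a group with no count was given a floor of 3 counts over the group. Intervals and floors cover counting error only.

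Genes were tested with edgeR 4.0.16 in R 4.3.3. TMM factors, the filterByExpr filter by group and 1 quasi-likelihood fit of all 12 libraries (legacy and robust settings on, 9 residual degrees of freedom) gave contrasts of Ehf IKO with Control OIL, with Control TMX and with the mean of both, and of Control TMX with Control OIL. The 15743 genes that passed the filter were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was called. On simulated data of this design with 100 genes changed 2-fold and 100 changed 4-fold, edgeR recovered 79% of the former and 100% of the latter in each comparison of Ehf IKO with 1 control, with 8 false calls each. DESeq2 recovered 84% and 85% of the genes changed 2-fold, with 21 and 25 false calls, and limma-voom 76% and 78%, with 3 and 9. The changed genes were drawn from those with an average log2 CPM above 1, and genes were simulated independently of each other. Recovery over all genes tested in these libraries may therefore be lower. A further small set of genes was shifted by less than 2-fold to test camera, and its recovery gene by gene was not measured.

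From 43 gene lists written from general knowledge, 41 had at least 5 tested members. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, then with an estimated correlation, and with fry, and adjusted over the lists within a comparison. The groups, tests, lists, first alternatives and rule for named genes were fixed before the data were examined. Named genes were Ehf, the 12 largest rises and 12 largest falls among genes called against both controls, the 6 smallest p among them, the 6 largest rises and falls between the controls, the 3 largest rises and falls called in 1 comparison of Ehf IKO with an unadjusted p above 0.2 in the other, and up to 4 members per list with the smallest p. Apart from list members, they had an average log2 CPM of at least 1 and no symbol of the Gm-number or Rik kind for the first and second sets. The genes beside Ehf fall outside the rule. Of the 12 largest rises, 1 is not reported here.

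Alternatives were DESeq2 size factors in edgeR, no filter, a mean log2 CPM of at least 1, DESeq2 1.42.0, limma-voom, the fit without its robust setting, a fit of the compared groups alone, the replicate number or the animal number as a block, a 2-fold minimum, scores of immune, colon region or sex markers as covariates, and leaving out each library in turn. The animal-number block was run in the fit of Control OIL and Ehf IKO alone. Scores of stromal, proliferation and clock genes as covariates were added after the data were seen. Comparisons between groups were also repeated over other splits of the libraries. Isoforms and exons were not analysed here, since the files hold whole-gene counts.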

Results

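RNA from the colonic epithelium of 12 C57BL/6 mice aged 6 weeks was sequenced, with 4 mice in each of 3 groups. Control OIL held mice labelled wild-type and given sunflower oil, whose source names begin with EVCER. Ehf IKO held mice with the same prefix, labelled as intestinal knockouts of Ehf and given tamoxifen. Ehf encodes an ETS-family transcription factor of epithelial cells. Control TMX held tamoxifen-treated mice labelled wild-type with the source VilCreER, a line with a tamoxifen-activated Cre recombinase under the Villin promoter, which the series text names as a further control for changes due to tamoxifen. The libraries held 7421411 to 10344161 counted reads, with a median of 8138352, and 15743 genes had enough counts to be tested. Levels are in CPM, counts scaled to library size with TMM factors, given as mean ± SD with n = 4 mice per group in the order Control OIL, Control TMX, Ehf IKO. Log2 fold changes are given ± SE from edgeR, and positions are on GRCm38. Xist and Y-linked genes placed replicates 1 and 2 of every group as female and replicates 3 and 4 as male. Mitochondrial genes took 10.7% to 26.3% of the counts per library and Gm26917 took 3.58% to 11.2%, with 95% Wilson intervals at most 0.0624 percentage points wide. In Ehf IKO replicate 2, 10.4% of the counts (95% Wilson interval 10.42% to 10.47%) fell in 12 satellite-like genes, against at most 0.114% in the other libraries.

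Ehf itself (ENSMUSG00000012350, chromosome 2, 103263433 to 103303278, minus strand) was counted at 428 ± 46.4, 345 ± 21.001 and 341 ± 30.1 CPM. Its log2 fold change in Ehf IKO was -0.33 ± 0.11 against Control OIL (edgeR adjusted p = 0.159) and -0.02 ± 0.11 against Control TMX (adjusted p = 0.972). The labels do not name the deleted exons and the counts are sums over all exons of the gene, so these values do not measure the deletion. DESeq2 called the difference from Control OIL (adjusted p = 0.0351, with 0.0351 to 0.688 over the alternatives other than the 2-fold minimum, which Ehf does not reach).

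Genes beyond the 3' end of Ehf had counts in the libraries labelled Ehf IKO and few or none in the controls. Gm13873 (ENSMUSG00000084385, a processed pseudogene on chromosome 2, 103232538 to 103232964, minus strand) lies 30469 bases beyond that end. It had 575 counts over the 4 Ehf IKO libraries, up to 184 in replicate 1, none in Control TMX and 1 in a single Control OIL library, which is at least 208-fold higher than Control TMX when the floor is 3 counts over the group. The lincRNA Gm13869 (ENSMUSG00000086957, same strand) had 27, 21, 9 and 21 counts in Ehf IKO and none in the 8 control libraries, at least 28.3-fold higher than Control TMX and at least 28.2-fold higher than Control OIL by the same floor. Gm13874 (ENSMUSG00000087032, a lincRNA on the plus strand) had 90 counts over the Ehf IKO libraries, 1 over Control TMX and 12 over Control OIL. In the edgeR test Gm13873 (adjusted p = 8.3e-09) and Gm13874 (adjusted p = 4.3e-04) rose against the mean of both controls, and Gm13869 held too few counts to be tested. On the other side of Ehf, up to Elf5, the annotated genes within 150000 bases held 12 counts over the 4 Ehf IKO libraries and 7 over the 8 control libraries. These genes were singled out after their values were seen, and floors cover counting error only.

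**Figure D1:**
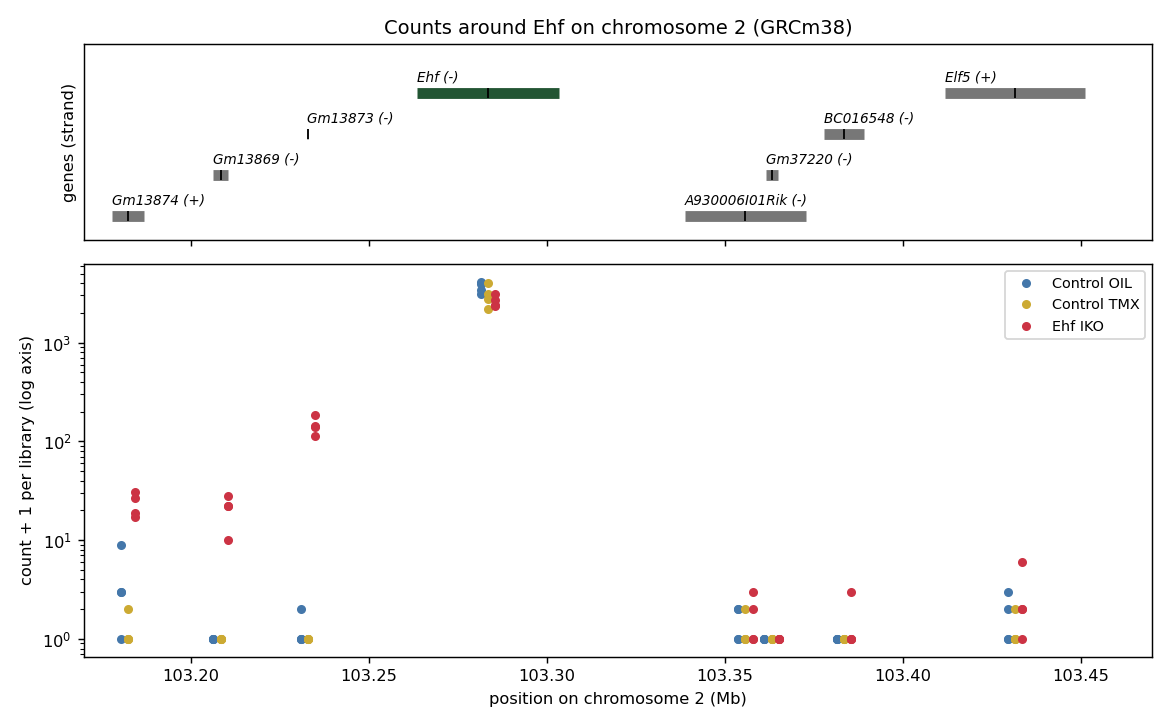
Annotated genes around Ehf on chromosome 2 (upper panel, position in Mb) and their read counts plus 1 per library on a log axis (lower panel), 1 point per library in each of the 3 groups. Gm13873 has 575 counts over the Ehf IKO libraries and 1 over the controls, while Ehf is counted in all 12 libraries.

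Cd177, Lpo and Ceacam10 fell in Ehf IKO against both controls. Cd177 (ENSMUSG00000052212, chromosome 7, 24743983 to 24760311), which encodes a GPI-anchored surface glycoprotein, was at 263 ± 51.2, 91.9 ± 10.7 and 6.82 ± 1.87 CPM, and fell by 4.51 ± 0.19 on the log2 scale against the mean of both controls (edgeR adjusted p = 2.9e-09). Lpo (ENSMUSG00000009356, chromosome 11, 87806428 to 87828289), which encodes the secreted enzyme lactoperoxidase, was at 26.1 ± 6.29, 19.3 ± 3.22 and 1.12 ± 0.392 CPM and fell by 4.29 ± 0.24 (adjusted p = 5.1e-08). Ceacam10 (ENSMUSG00000054169, chromosome 7, 24777206 to 24784657), of the carcinoembryonic antigen family, was at 29.0 ± 4.54, 7.33 ± 1.11 and 1.29 ± 1.04 CPM and fell by 3.51 ± 0.30 (adjusted p = 1.9e-05). Plet1 (ENSMUSG00000032068, chromosome 9, 50494525 to 50505482), which encodes an epithelial surface protein, was at 54.5 ± 19.8, 36.0 ± 1.58 and 8.79 ± 3.77 CPM and fell by 2.32 ± 0.28 (adjusted p = 9.0e-04). Its antisense gene Plet1os fell by 2.52 ± 0.44, but the counts are unstranded and the 2 genes overlap, so neither value is sure to belong to its gene alone. The collagen gene Col8a1 fell by 2.44 ± 0.33, from 37.2 ± 16.8 and 26.2 ± 6.43 to 5.78 ± 2.42 CPM. The sodium channel subunit gene Scn2b (-3.12 ± 0.38), the noncoding RNA gene Meg3 (-1.80 ± 0.30), the VIP receptor gene Vipr2 (-1.74 ± 0.28), Sptbn4 (-1.74 ± 0.33), Insrr (-1.72 ± 0.29) and Smim38 (-1.54 ± 0.25) made up the rest of the 12 largest falls. Among the 6 smallest p were also St6galnac6, a sialyltransferase gene that fell by 1.02 ± 0.09 from 495 ± 18.0 and 454 ± 57.2 to 234 ± 7.65 CPM (adjusted p = 2.6e-05), and Pglyrp1, for a peptidoglycan recognition protein, which fell by 1.32 ± 0.13 (adjusted p = 8.4e-05). Cd177, Lpo, Ceacam10, Plet1, Col8a1, St6galnac6 and Pglyrp1 were each lower in all 4 Ehf IKO libraries than in any of the 8 control libraries. Meg3 lost its call with the replicate number as a block (adjusted p = 0.0624, with 4.8e-09 to 0.0624 over all alternatives) and Sptbn4 without Ehf IKO replicate 1 (adjusted p = 0.0667, with 6.8e-09 to 0.0667).

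Reg4, Alpi and Trpv6 were among the genes that rose in Ehf IKO against both controls. Reg4 (ENSMUSG00000027876, chromosome 3, 98222156 to 98236748), a secreted lectin that marks deep crypt secretory cells of the mouse colon, was at 71.8 ± 19.1, 62.1 ± 24.1 and 274 ± 84.8 CPM and rose by 2.03 ± 0.23 against the mean of both controls (edgeR adjusted p = 7.4e-04). Alpi (ENSMUSG00000079440, chromosome 1, 87098002 to 87101606), the intestinal alkaline phosphatase gene, was at 15.5 ± 4.69, 33.4 ± 4.42 and 81.2 ± 22.9 CPM and rose by 1.82 ± 0.18 (adjusted p = 1.0e-04). Trpv6 (ENSMUSG00000029868, chromosome 6, 41620624 to 41636405), an epithelial calcium channel gene, was at 14.0 ± 5.25, 19.9 ± 2.77 and 60.1 ± 22.0 CPM and rose by 1.85 ± 0.24 (adjusted p = 0.00213). Rab3b (1.96 ± 0.32) and Syt8 (1.94 ± 0.23), both of families that act in vesicle release, rose as well, to 6.36 ± 1.99 and 9.24 ± 2.09 CPM. The mast cell chymase gene Cma1 rose by 3.42 ± 0.47, from 0.785 ± 0.728 and 0.480 ± 0.367 to 6.88 ± 4.199 CPM. Fmo1 (2.38 ± 0.32), Pkib (2.32 ± 0.33), Ambp (2.21 ± 0.23), Pla2g2a (1.88 ± 0.29) and Id4 (1.68 ± 0.20) were also among the 12 largest rises, of which Pla2g2a is annotated as a polymorphic pseudogene. Each of the genes named here was higher in all 4 Ehf IKO libraries than in any of the 8 control libraries. Close gene families, such as Ceacam, alkaline phosphatases and mast cell proteases, hold uniquely mapped reads alone.

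**Figure D2:**
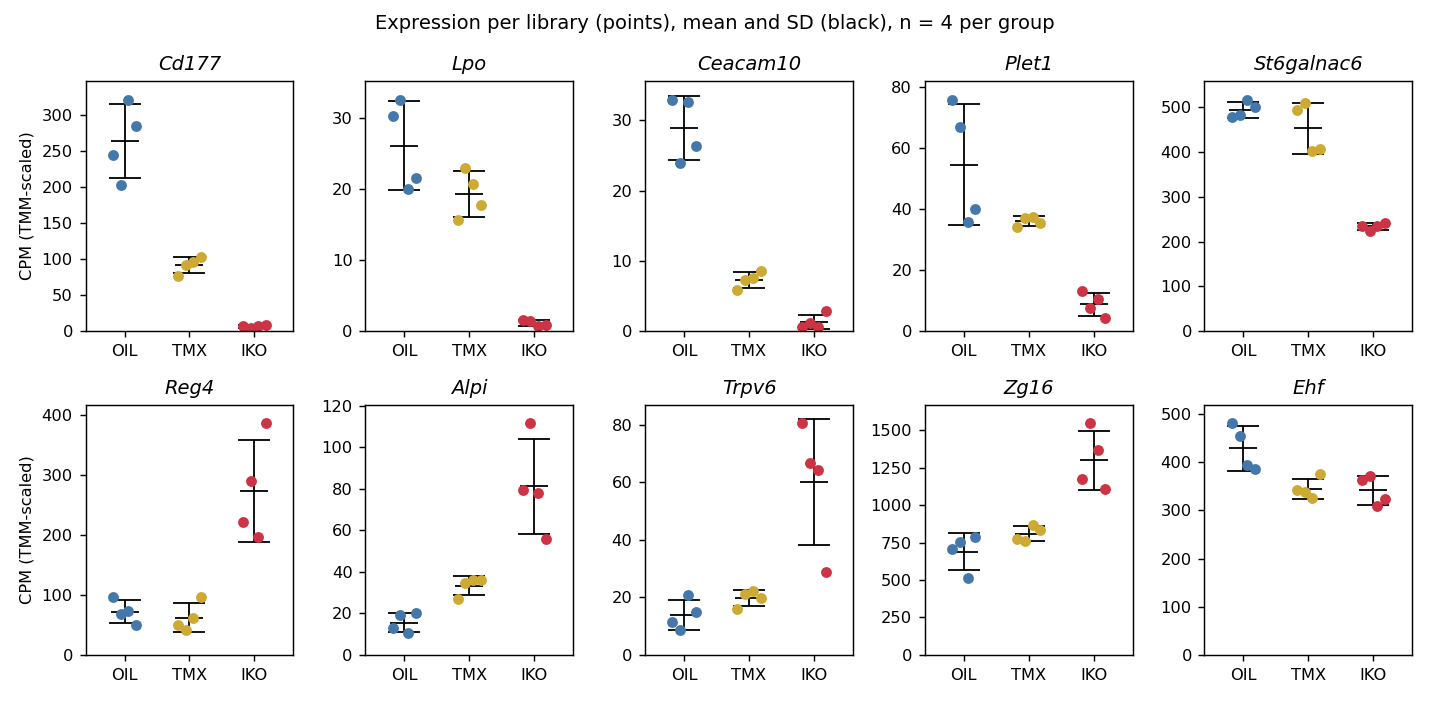
TMM-scaled CPM per library for 10 genes in Control OIL, Control TMX and Ehf IKO, with 1 point per library and the mean and SD in black. Cd177, Lpo, Ceacam10, Plet1 and St6galnac6 are lower and Reg4, Alpi, Trpv6 and Zg16 higher in all 4 Ehf IKO libraries than in any control library, while Ehf overlaps with Control TMX.

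**Figure D3:**
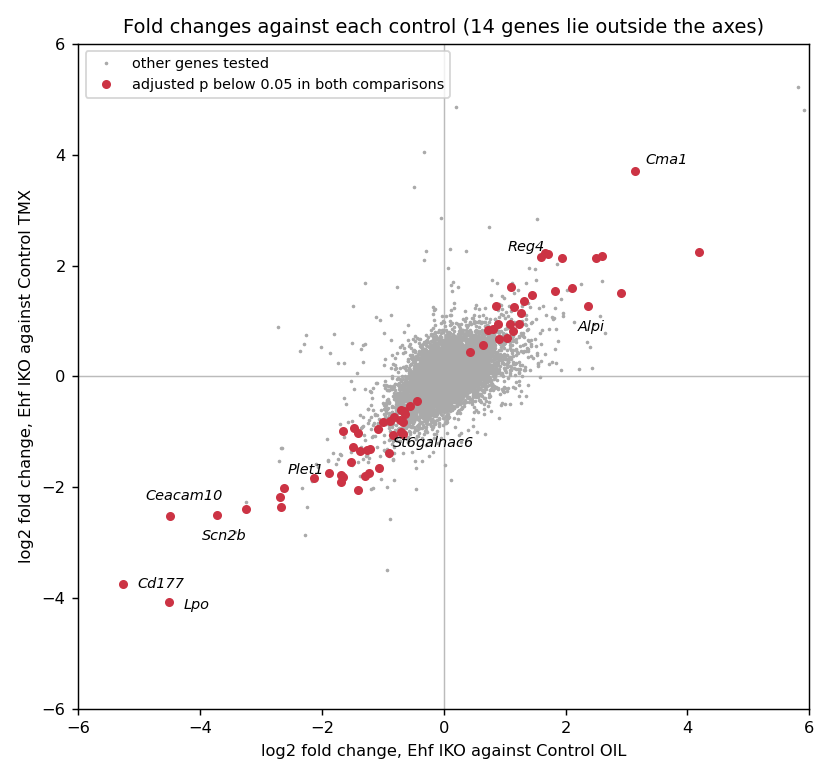
Log2 fold change of each tested gene in Ehf IKO against Control OIL (horizontal) and against Control TMX (vertical), with the genes called in both in red. All 70 genes called in both comparisons have the same sign in both, and 14 genes, among them Gm13873 and Gm13874, lie outside the axes, which end at 6.

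Secretory gene groups moved in different directions. Of 9 measured genes of deep crypt secretory and Paneth cells, 3 rose against the mean of both controls (Reg4, Pla2g2a and Spink4) and 6 did not pass the test. The list had 4 rises adjusted over the list alone, and camera called the list higher (adjusted p = 6.6e-05, and adjusted p = 0.132 with an estimated correlation). Of 26 genes of mucin O-glycosylation and mucus secretion, 19 were lower, 3 fell (St6galnac6, Galnt12 and Ern2) and none rose. There were 6 falls adjusted over the list alone, and camera called the list lower (adjusted p = 6.6e-04, and adjusted p = 0.124 with an estimated correlation). Of 24 goblet cell genes, 2 rose and 4 fell, or 3 and 5 adjusted over the list alone, and camera did not call the list (adjusted p = 0.669, and adjusted p = 0.884 with an estimated correlation). The goblet cell lectin gene Zg16 (ENSMUSG00000049350) was at 689.7 ± 124, 810.5 ± 49.1 and 1299.7 ± 198 CPM and rose by 0.80 ± 0.12 (adjusted p = 0.00242). Spdef, an ETS-family gene needed for goblet cell maturation, fell by 0.92 ± 0.18, from 94.7 ± 25.6 and 111 ± 31.3 to 54.0 ± 4.54 CPM. Spdef was also the 1 gene of 18 ETS-family genes that passed, over all genes and adjusted over the list alone (camera adjusted p = 0.604, and adjusted p = 0.760 with an estimated correlation). Against Control OIL none of the 18 passed over all genes, and 1 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.822, and adjusted p = 0.854 with an estimated correlation). Of 20 enteroendocrine genes, 19 were lower and 1 fell, the granin gene Chga, by 0.76 ± 0.12 to 46.5 ± 4.67 CPM (adjusted p = 0.00327). Chga was at 53.9 to 78.8 CPM in the Control OIL libraries and at least 86.3 in those of Control TMX, so Control TMX was the high group. Of the list, 2 genes fell adjusted over the list alone, and camera called the list lower (adjusted p = 6.6e-05, and adjusted p = 0.357 with an estimated correlation). Against Control OIL, 14 of the 20 were lower and 6 higher, and 1 fell over all genes, Tac1 rather than Chga. Tac1 lost this call in most of the 12 fits that leave out 1 library (up to adjusted p = 0.134). Adjusted over the list alone 2 fell (camera adjusted p = 0.00581, and adjusted p = 0.440 with an estimated correlation). Of 20 tuft cell genes 1 rose, Dclk1 (0.72 ± 0.16), and 3 adjusted over the list alone (camera adjusted p = 0.0260, and adjusted p = 0.746 with an estimated correlation). Against Control TMX, 14 of the tuft genes were higher and none passed, over all genes or adjusted over the list alone (camera adjusted p = 0.166, and adjusted p = 0.910 with an estimated correlation). Against Control OIL 15 were higher, none passed over all genes and 1 rose adjusted over the list alone (camera adjusted p = 0.00784, and adjusted p = 0.467 with an estimated correlation). Spdef lost its call without Ehf IKO replicate 1, 2 or 3 (up to adjusted p = 0.0789), and Spink4, Galnt12, Ern2 and Dclk1 lost theirs in most of the 12 fits that leave out 1 library (up to adjusted p = 0.118, 0.173, 0.141 and 0.111). The stromal score ended the calls of Spdef, Spink4, Galnt12 and Ern2 (up to adjusted p = 0.190), and the replicate block those of Galnt12, Ern2 and Dclk1 (up to adjusted p = 0.119). The tuft list lost its camera call without Control OIL replicate 4 or Ehf IKO replicate 3 or 4 (up to adjusted p = 0.195).

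The colonocyte, keratin and fetal-like lists were mostly higher in Ehf IKO with few single calls, and tight junctions and sodium and chloride transport were mixed. Of 38 genes of differentiated colonocytes, 31 were higher and 1 rose, the magnesium channel gene Trpm6, by 0.68 ± 0.12 to 317 ± 23.1 CPM. In this list 3 genes rose adjusted over the list alone, and camera called the list higher (adjusted p = 0.00199, and adjusted p = 0.746 with an estimated correlation). The score of this list was 0.30, 0.40 and 0.19 in Ehf IKO replicates 1 to 3 and -0.35 in replicate 4, against -0.24 ± 0.20 in Control OIL and 0.10 ± 0.11 in Control TMX. Against Control OIL, 34 of these 38 were higher, 2 rose and 11 rose adjusted over the list alone (camera adjusted p = 4.9e-07, and adjusted p = 0.384 with an estimated correlation). Against Control TMX, 20 were higher and 18 lower, none passed in edgeR, and 1 rose adjusted over the list alone (camera adjusted p = 0.767, and adjusted p = 0.976 with an estimated correlation). In Control TMX against Control OIL, 30 of the 38 were higher, none passed in edgeR and 4 rose adjusted over the list alone (camera adjusted p = 5.7e-06, and adjusted p = 0.490 with an estimated correlation). Of 14 keratin and cornification genes, 13 were higher and 2 rose, the desmoglein gene Dsg3 (1.55 ± 0.30, to 3.23 ± 1.41 CPM) and Sfn (0.42 ± 0.10, to 91.8 ± 12.5 CPM). A total of 7 rose adjusted over the list alone, and camera called the list higher (adjusted p = 2.2e-06, and adjusted p = 0.124 with an estimated correlation). Of 20 genes of the fetal-like and YAP-associated repair programme, 18 were higher, 1 rose and 6 rose adjusted over the list alone (camera adjusted p = 1.4e-04, and adjusted p = 0.124 with an estimated correlation). The gene that rose was Cldn4, a claudin gene, at 47.0 ± 11.3, 67.6 ± 19.9 and 114 ± 33.8 CPM. Against Control TMX, 13 of the 14 keratin and 19 of the 20 fetal-like genes were higher and none passed over all genes. Adjusted over the list alone 3 and 1 rose (camera adjusted p = 3.6e-04 each, and adjusted p = 0.249 and 0.172 with an estimated correlation). Replicate 4 was also the lowest Ehf IKO library for the keratin list (score 0.01) and the fetal-like list (-0.07). Of 28 tight junction genes, 14 were higher and 14 lower, and Cldn4 alone passed. The median of the list was -0.00, its mean was 0.04, and 2 genes rose and 1 fell adjusted over the list alone (camera adjusted p = 0.604, and adjusted p = 0.770 with an estimated correlation). Against Control TMX no tight junction gene passed, over all genes or adjusted over the list alone (camera adjusted p = 0.948, and adjusted p = 0.976 with an estimated correlation). Of 28 genes of sodium and chloride transport, 13 were higher and 15 lower, and the sodium channel subunit gene Scnn1b fell by 1.37 ± 0.26 to 4.11 ± 1.03 CPM. The median of the list was -0.04, its mean was 0.02, and 1 gene rose and 2 fell adjusted over the list alone (camera adjusted p = 0.730, and adjusted p = 0.870 with an estimated correlation). Among 16 proximal colon markers, the folate hydrolase gene Ggh fell by 1.22 ± 0.13, from 93.7 ± 10.6 and 71.9 ± 10.9 to 35.2 ± 6.65 CPM (adjusted p = 1.2e-04), while Cbr3 rose by 0.65 ± 0.12. Adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.622, and adjusted p = 0.760 with an estimated correlation). Of 13 distal colon markers, 11 were lower against Control OIL and 1 fell, or 2 adjusted over the list alone (camera adjusted p = 0.0267, and adjusted p = 0.355 with an estimated correlation). Against Control TMX 7 were higher and 6 lower, and 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.767, and adjusted p = 0.976 with an estimated correlation). Against the mean of both controls none of 21 stem cell genes passed in edgeR, and adjusted over the list alone 3 fell (camera adjusted p = 0.187, and adjusted p = 0.760 with an estimated correlation). Against Control OIL, 13 of the 21 were lower and 1 fell, or 2 adjusted over the list alone (camera adjusted p = 0.0204, and adjusted p = 0.614 with an estimated correlation). Against Control TMX, 11 were higher and 10 lower, and none passed, over all genes or adjusted over the list alone (camera adjusted p = 0.907, and adjusted p = 0.976 with an estimated correlation). Trpm6 and Scnn1b lost their calls without Ehf IKO replicate 3 (adjusted p = 0.0544 and 0.0575), Cbr3 without Ehf IKO replicate 1 (adjusted p = 0.0532) and Dsg3 without Ehf IKO replicate 1, 2 or 3 (up to adjusted p = 0.0840). Sfn and Cldn4 lost theirs in most fits that leave out 1 library (up to adjusted p = 0.198 and 0.141). The stromal score ended the calls of Trpm6, Dsg3, Sfn and Cldn4 (up to adjusted p = 0.267), and the replicate block those of Dsg3, Sfn and Cldn4. The colonocyte list lost its camera call without Ehf IKO replicate 2 (adjusted p = 0.123).

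Markers of other cell types moved with the groups as well. Of 20 fibroblast and matrix genes, 19 were higher in Ehf IKO than the mean of both controls and none passed over all genes in edgeR, while 11 rose and 1 fell adjusted over the list alone (camera adjusted p = 5.2e-06, and adjusted p = 0.415 with an estimated correlation). The mean centred log2 CPM of these genes was -0.37 ± 0.06 in Control OIL, 0.11 ± 0.23 in Control TMX and 0.26 ± 0.36 in Ehf IKO. Of 18 genes of macrophages, dendritic cells and granulocytes 1 rose, the mannose receptor gene Mrc1, by 1.21 ± 0.22 to 6.67 ± 1.53 CPM. Adjusted over the list alone 1 rose (camera adjusted p = 0.0313, and adjusted p = 0.528 with an estimated correlation). Against Control OIL, 12 of the 18 were higher and 1 rose, and adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.247, and adjusted p = 0.614 with an estimated correlation). Of 22 genes of antimicrobial defence, 3 rose (Zg16, Pla2g2a and Duoxa2) and Wfdc18 fell by 2.76 ± 0.52 to 0.459 ± 0.407 CPM. With 6 rises and 2 falls adjusted over the list alone, camera called the list higher (camera adjusted p = 0.0425, and adjusted p = 0.579 with an estimated correlation). Against Control OIL, 10 were higher and 12 lower, 2 rose and 2 fell, and 2 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.483, and adjusted p = 0.822 with an estimated correlation). The score of this list was 0.31 ± 0.30, -0.46 ± 0.09 and 0.15 ± 0.19 in the 3 groups. Of 42 proliferation genes, 32 were higher and none passed in edgeR or adjusted over the list alone (camera adjusted p = 0.0313, and adjusted p = 0.770 with an estimated correlation). Against Control OIL, 20 were higher and 22 lower, and again none passed, over all genes or adjusted over the list alone (camera adjusted p = 0.152, and adjusted p = 0.854 with an estimated correlation). Of 20 immediate early and dissociation response genes, 14 were higher against the mean and 2 rose (camera adjusted p = 0.0486, and 0.711 with an estimated correlation). Against Control OIL, 15 were higher and 2 rose (camera adjusted p = 0.00662, and 0.384 with an estimated correlation). Adjusted over the list alone 3 rose in each. Against Control TMX, 10 were higher and 10 lower, and none passed (camera adjusted p = 0.507, and 0.953 with an estimated correlation). Of the 41 lists tested against the mean of both controls, camera called 17, 14 of them higher, and with an estimated correlation called 0, with 4 lists at an unadjusted p under 0.05. By fry 5 lists moved on balance one way and 19 held changes in either direction. Without Ehf IKO replicate 1, Mrc1 (adjusted p = 0.0709) and Wfdc18 (adjusted p = 0.0652) lost their calls, and Duoxa2 lost its call without Ehf IKO replicate 1 or 3 (up to adjusted p = 0.0805). The stromal score ended the calls of Mrc1, Wfdc18 and Duoxa2 (up to adjusted p = 0.212). By camera, the proliferation list lost its call without Control TMX replicate 1 or 2, Control OIL replicate 2 or 4 or Ehf IKO replicate 3 or 4 (up to adjusted p = 0.757). The macrophage list lost its call without Control TMX replicate 4, Control OIL replicate 2 or 4 or Ehf IKO replicate 1, 2 or 3 (up to 0.167), and the antimicrobial list without Control TMX replicate 4, Control OIL replicate 2 or Ehf IKO replicate 1 or 3 (up to 0.174).

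**Figure D4:**
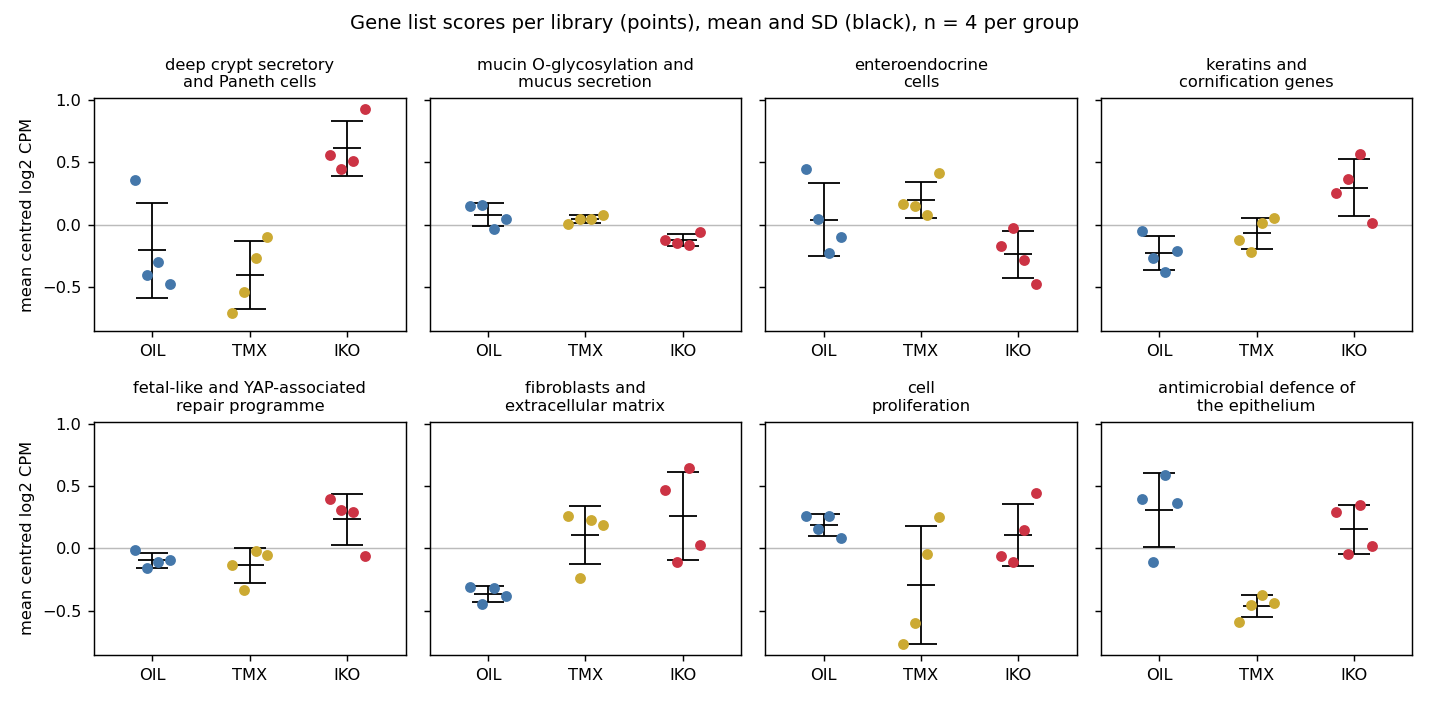
Mean centred log2 CPM of 8 gene lists per library, with 1 point per library in each of the 3 groups and the mean and SD in black. The fibroblast score is lower in every Control OIL library than in any library of the other groups, and its mean is 0.26 in Ehf IKO and 0.11 in Control TMX.

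In all, 265 genes differed between Ehf IKO and Control OIL (145 higher, 120 lower) and 126 between Ehf IKO and Control TMX (52 higher, 74 lower) by edgeR at an adjusted p under 0.05. Both comparisons called 70 genes with the same sign, 30 higher and 40 lower, and 0 with opposite signs. Against the mean of both controls 270 genes passed, as many higher as lower, 117 of them at 2-fold or more. Both comparisons share the Ehf IKO libraries, so chance alone relates them. Across genes, which are not independent replicates, their fold changes correlated at 0.615, against 0.508 in 20 simulations with no group effect. Independent lists of these lengths would share 0.479 genes higher and 0.564 lower. The simulations called a mean of 0.15 and 0 genes, too few to measure an overlap. With the Ehf IKO libraries split into pairs, so that no library served in both comparisons, the 6 ways of splitting shared 3 to 14 genes higher and 6 to 18 lower, at correlations of -0.00914 to 0.371. The 70 genes became 31 with the stromal score as a covariate, 42 with a fold of at least 2 required and 229 with no low-count filter, and 1.4e+02 by DESeq2. They became 40 without Control TMX replicate 2, 36 without Control TMX replicate 3, and 41, 42, 37 and 106 without Ehf IKO replicates 1 to 4. The 270 genes became 148 with the replicate block, 148 with the stromal score, 413 with the proliferation score, 441 by DESeq2 and 831 with no filter. They became 125, 108 and 522 without Ehf IKO replicates 1, 3 and 4, and 1.4e+02 without replicate 2 (values in powers of 10 are rounded to 2 digits).

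The comparison with Control OIL, whose source names share the prefix of the knockouts, changes Ehf status and tamoxifen together. Of the 265 genes, 31 had an unadjusted p above 0.2 against Control TMX. Among those 31, the calcium-binding protein gene S100g rose by 1.93 ± 0.37, at 12.7 ± 5.36, 43.9 ± 17.7 and 47.5 ± 15.2 CPM (edgeR adjusted p = 0.0243). Cpn1 rose by 1.78 ± 0.35 and Rfx2 by 1.66 ± 0.35, while Gm45397 fell by 1.73 ± 0.36, the adenylate kinase gene Ak4 by 1.47 ± 0.29, from 28.9 ± 9.30 to 10.3 ± 4.01 CPM, and the mucin gene Muc1 by 1.11 ± 0.26. Of 20 fibroblast and matrix genes, 19 were higher and 5 rose, such as Col3a1, from 136 ± 10.5 to 281 ± 93.2 CPM, and Sparc, from 9.71 ± 1.96 to 18.2 ± 4.06 CPM. Adjusted over the list alone 12 rose (camera adjusted p = 5.1e-10, and adjusted p = 0.283 with an estimated correlation). All 20 were higher in Control TMX than Control OIL, none passed over all genes and 7 rose adjusted over the list alone (camera adjusted p = 3.8e-07, and adjusted p = 0.412 with an estimated correlation). Against Control TMX, 18 were higher in Ehf IKO, and none passed over all genes or adjusted over the list alone (camera adjusted p = 0.178, and adjusted p = 0.944 with an estimated correlation). Of 23 genes of the unfolded protein response, 21 were lower and Asns fell by 0.84 ± 0.16. Adjusted over the list alone 6 fell (camera adjusted p = 5.9e-06, and adjusted p = 0.355 with an estimated correlation). In Control TMX against Control OIL, 20 of the 23 were lower, none passed over all genes and 12 fell adjusted over the list alone (camera adjusted p = 2.1e-07, and adjusted p = 0.412 with an estimated correlation). Against Control TMX, 15 were higher and 8 lower in Ehf IKO, and Ern2 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.522, and adjusted p = 0.976 with an estimated correlation). All 7 MHC class II genes were lower, none passed over all genes and 7 fell adjusted over the list alone (camera adjusted p = 8.2e-04, and adjusted p = 0.438 with an estimated correlation). Their score was 0.87 ± 1.41, -0.65 ± 0.42 and -0.22 ± 0.11 in the 3 groups. In Control TMX against Control OIL all 7 were lower as well, none passed over all genes and 7 fell adjusted over the list alone (camera adjusted p = 1.8e-05, and adjusted p = 0.413 with an estimated correlation). Against Control TMX, 6 of 7 were higher in Ehf IKO, and none passed over all genes or adjusted over the list alone (camera adjusted p = 0.474, and adjusted p = 0.976 with an estimated correlation). Control OIL replicate 3 stood apart at 2.77, with 1.07, -0.49 and 0.15 in replicates 1, 2 and 4, and replicate 2 lay below every Ehf IKO library. Without Ehf IKO replicate 3, S100g, Cpn1, Rfx2, Gm45397, Ak4, Muc1, Col3a1, Sparc and Asns lost their calls, and each but Ak4 did so without Ehf IKO replicate 1 as well (up to adjusted p = 0.123 over all fits that leave out 1 library). The stromal score ended the calls of all 9 (up to adjusted p = 0.810). Under it the log2 fold changes of Cpn1, Rfx2, Gm45397, Sparc, Asns, Col3a1 and S100g were smaller (0.81, 0.46, -0.80, 0.42, -0.66, 0.86 and 1.52), and those of Ak4 and Muc1 lay further from 0 than without it. The stromal score was -0.27 or lower in Control OIL and higher in the other libraries but Ehf IKO replicate 4 (-0.27), so it is tied to the groups compared. It was made from the fibroblast and smooth muscle lists, and Col3a1 and Sparc are members of the former. For these genes the loss of the call under the score is therefore no test. The colon region score ended all of these calls but those of Ak4 and Asns. The fit of these groups alone ended all but those of S100g and Asns, and with the animal-number block added it ended those of Cpn1, Rfx2 and Muc1. The 265 genes became 35 with the stromal score as a covariate, 173 with the replicate block, 128 at 2-fold or more and 438 with the proliferation score. They became 491 with the clock score, 491 by DESeq2, 724 with no filter and 322 with sex in the fit of all 12 libraries. With these groups alone in the fit they became 1.1e+02, and 174 when the animal-number block was added to that fit. They became 174 and 149 without Control OIL replicates 1 and 3, 1.4e+02 without replicate 4, and 104, 130, 105 and 711 without Ehf IKO replicates 1 to 4.

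The comparison with Control TMX holds tamoxifen fixed and changes Ehf status and line together. Of its 126 genes, 12 had an unadjusted p above 0.2 against Control OIL. Nos2, the inducible nitric oxide synthase gene, was at 34.5 ± 4.70, 5.84 ± 2.96 and 28.1 ± 8.20 CPM and rose by 2.26 ± 0.30 (edgeR adjusted p = 0.00232). Duoxa2, which encodes the maturation factor of an epithelial oxidase, was at 18.6 ± 1.85, 6.29 ± 1.69 and 20.6 ± 6.05 CPM and rose by 1.71 ± 0.22 (adjusted p = 0.00183). The lincRNA Gm21718 was at 5.61 ± 1.96 CPM in Ehf IKO, 6.57 ± 5.43 in Control OIL and not counted in Control TMX. Gm2061 fell by 1.19 ± 0.25, Aplp1 by 0.90 ± 0.15 and Sned1 by 0.71 ± 0.15. Gm21718 lost its call without Ehf IKO replicate 2 (adjusted p = 0.0527), and Gm2061 and Sned1 lost theirs in most fits that leave out 1 library (up to adjusted p = 0.116 and 0.119). The replicate block ended the calls of Gm21718, Gm2061 and Sned1 (adjusted p = 0.0673, 0.102 and 0.0825), and the clock score those of Gm2061, Aplp1 and Sned1 (adjusted p = 0.115, 0.0574 and 0.262). The immune score ended those of Gm21718 and Sned1 (up to adjusted p = 0.178). Of 22 genes of antimicrobial defence, 19 were higher and 4 rose, and adjusted over the list alone 9 rose and 2 fell (camera adjusted p = 2.9e-05, and adjusted p = 0.172 with an estimated correlation). Of 20 enteroendocrine genes, 18 were lower and Chga fell by 1.07 ± 0.13, while adjusted over the list alone 4 fell (camera adjusted p = 2.9e-05, and adjusted p = 0.253 with an estimated correlation). Of 42 proliferation genes, 40 were higher and none passed, over all genes or adjusted over the list alone (camera adjusted p = 4.5e-08, and adjusted p = 0.667 with an estimated correlation). The female Control TMX replicates 1 and 2 had scores of -0.77 and -0.60, while the male replicates 3 and 4 (-0.05 and 0.25) lay within the range of Ehf IKO (-0.11 to 0.44). The 126 genes became 72 with the replicate block, 73 with the immune score, 83 with the clock score, 223 with the colon region score, 70 at 2-fold or more, 281 by DESeq2 and 500 with no filter. They became 72, 53 and 50 without Control TMX replicates 1 to 3, and 71, 66 and 59 without Ehf IKO replicates 1 to 3.

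The control groups differ in tamoxifen and line together, and 13 genes differed between them, 6 higher and 7 lower in Control TMX. Nos2 fell by 2.55 ± 0.30 on the log2 scale (edgeR adjusted p = 0.00404), Ceacam10 fell by 1.97 ± 0.25 (adjusted p = 0.00404), Duoxa2 by 1.56 ± 0.22 (adjusted p = 0.0129) and Cd177 by 1.52 ± 0.16 (adjusted p = 0.0020). Lyrm7 fell by 1.40 ± 0.20 and Tnip3 by 1.07 ± 0.18. The manganese exporter gene Slc30a10 rose by 1.55 ± 0.24, from 31.6 ± 10.6 to 92.7 ± 15.0 CPM (adjusted p = 0.0413), Ppargc1a by 0.92 ± 0.15, Irs2 by 0.81 ± 0.14, Ptprs by 0.79 ± 0.13 and the cytochrome reductase gene Por by 0.73 ± 0.13. Of 42 proliferation genes, 40 were lower in Control TMX, none passed over all genes in edgeR and 9 fell adjusted over the list alone (camera adjusted p = 2.0e-12, and adjusted p = 0.481 with an estimated correlation). As above, the low scores were those of the female Control TMX replicates, and those of Control OIL were 0.08 to 0.26. Of 15 smooth muscle and pericyte genes, 14 were higher, none passed over all genes and 10 rose adjusted over the list alone (camera adjusted p = 1.2e-07, and adjusted p = 0.412 with an estimated correlation). Of 22 genes of antimicrobial defence, 19 were lower and 2 fell, Nos2 and Duoxa2, while adjusted over the list alone 8 fell (camera adjusted p = 2.0e-07, and adjusted p = 0.178 with an estimated correlation). With the stromal score as a covariate Nos2 (adjusted p = 0.0337) and Duoxa2 (adjusted p = 0.0110) kept their calls, and the other named genes lost theirs. These were Ceacam10 (log2 fold change -0.63, adjusted p = 0.954), Cd177 (-1.29, adjusted p = 0.518), Lyrm7 (-1.40, adjusted p = 0.436), Tnip3 (-1.31, adjusted p = 0.378) and the 5 rises (adjusted p = 0.954 each, Slc30a10 at 0.90). The stromal score was -0.58 to -0.27 in the Control OIL libraries and 0.08 to 0.33 in those of Control TMX. It separates the groups compared, so a call lost under it is no test of these genes. The proliferation score ended the calls of Duoxa2, Tnip3 and the 5 rises (up to adjusted p = 0.286), and the clock score those of Tnip3 and the 5 rises (up to adjusted p = 0.106). The 5 named rises and Tnip3 each lost their call in at least 7 of the 12 fits that leave out 1 library (up to adjusted p = 0.165), Duoxa2 without Control TMX replicate 1 or 2 and Lyrm7 without Control TMX replicate 2 (up to 0.0706). The 13 genes became 5 with the stromal score or with a mean log2 CPM of at least 1, 6 with the proliferation score, 8 by limma-voom, 23 with the colon region score, 38 with sex, 186 by DESeq2 and 441 with no filter. They became 8, 66 and 8 without Control OIL replicates 1 to 3, 4, 3, 5 and 48 without Control TMX replicates 1 to 4, and 5, 5, 5 and 67 without Ehf IKO replicates 1 to 4.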

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

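The tests of genomic DNA, of the unrecombined line, of tamoxifen or the recombinase and of transcription past Ehf for the counts below Ehf, of satellite transcription for Ehf IKO replicate 2 and of sex for the clock genes were chosen only after the result was seen, and those of other splits, of genomic DNA in the RNA of Ehf IKO replicate 2 and of time of day were planned.

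In Ehf IKO replicate 2, 10.44% of the counts fell in satellite-like genes (95% Wilson interval 10.42% to 10.47%), far from 0.0405% to 0.109% in the other Ehf IKO libraries. Without the satellite-like genes, 5866 genes were seen in this library alone, against at most 277 in any other library, which argues against transcription of satellite repeats alone. Of autosomal genes silent in the other libraries, 12.7%, 29.7% and 55.0% had a count here from the shortest to the longest exon length class, a ratio of 4.34, and a candidate explanation is genomic DNA in the RNA. None of 1549 Y-linked genes was seen, but that part has little force, as Y genes counted in males were left out and Y repeats map to several places. No other biological explanation was tested.

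The 3 genes below the 3' end of Ehf held 743 counts in the Ehf IKO libraries and 14 in the controls. Genomic DNA is argued against by the lowest sum, 1.4e+02 counts (rounded to 2 digits), in the Ehf IKO libraries without the satellite excess, and tamoxifen or the recombinase alone by at most 1 in a Control TMX library. The modified Ehf line before recombination stays open: Control OIL held at most 8 counts in a library but is labelled wild-type. Transcription past the end of a recombined Ehf gene may be the source, and it cannot be told apart from other sources, since genes on the other side of Ehf were 3.43 times as high per library, just over the bound of 3. That ratio rests on 12 counts against 7, most of the 12 in Ehf IKO replicate 2.

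The clock score, high Per, Dbp and Nr1d genes less Arntl and its partners, was 3.29 higher in female than male Control TMX libraries, 2 libraries per sex. In Control OIL the female minus male value was -2.03 and in Ehf IKO 0.954, which argues against a sex difference common to all groups. The values cannot decide on a sex difference that itself differs between the groups, with 2 libraries per sex in each. Another time of day at collection could be the source and stays open. Of 4 clock-controlled genes off the list, 2 were higher in the female Control TMX libraries by edgeR (Usp2 and Cipc, adjusted p = 3.8e-04 each), and Wee1 and Tspan4 did not pass (adjusted p = 0.345 each). Collection times are not given in the sources used here.

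A library far from the other 3 of its group was found for 14 of 291 group values, where chance gives 14.6. Most of these values are of genes named for their change or small p, so the number from chance is a rough guide. Of the 14, 8 lay in Ehf IKO, most of them in replicate 4, with 4 in Control TMX and 2 in Control OIL. In Control TMX replicate 2, Scn2b was 4.573 CPM (others 2.118 to 2.431), Sptbn4 8.651 (4.661 to 5.236) and Scnn1b 15.33 (8.698 to 9.162), and in Control TMX replicate 3 Pkib was 1.483 (0.7766 to 0.8651). In Ehf IKO replicate 4, Meg3 was 7.657 CPM (others 20.15 to 21.55), Cma1 13.16 (4.416 to 5.008), Fmo1 12.63 (4.775 to 5.587), Gm45397 2.149 (0.9661 to 1.064), Cldn23 31.7 (45.82 to 47.4) and Mylk 31.84 (47.17 to 49.13). Sfn was 110.4 CPM in Ehf IKO replicate 3 (others 83.78 to 86.78), Ggh 109.5 in Control OIL replicate 1 (87.14 to 90.3) and Trp53inp1 49.81 in Control OIL replicate 3 (60.5 to 62.52).

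By an edgeR interaction term with 2 libraries per sex and group, the difference between groups differed between males and females for 49 genes in Ehf IKO against Control OIL, 11 against Control TMX and 708 in Control TMX against Control OIL. Against the mean of both controls it did so for 0 genes, with 2481 at an unadjusted p under 0.05, and no other tool was run. For Dbp in Control TMX against Control OIL the log2 fold change was -0.97 in males and 4.96 in females, and for Ces1d in Ehf IKO against Control OIL it was 1.41 in males and -0.74 in females. Between the controls, this term sets Control TMX males and Control OIL females against the other control libraries. The clock score separates the same libraries, so for the 708 genes sex cannot be told apart from it.

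Other splits of the libraries gave up to 279 genes where Ehf IKO against Control OIL gave 265 (2 of 35 splits as large). They gave up to 75 where Control TMX against Control OIL gave 13 (2 of 35), so chance is not excluded for either. The 279 came from exchanging Ehf IKO replicate 4 with Control OIL replicate 4. The same exchange with Control OIL replicate 2 gave 110, and with replicate 1 or 3 gave 0. Without Ehf IKO replicate 4, Ehf IKO against Control OIL called 711 genes, so the count depends on where that library is placed. The 75 came from Control TMX replicates 3 and 4 with Control OIL replicates 1 and 2, against the other control libraries. The clock score was -1.65 to -0.09 in the former and 0.18 to 2.90 in the latter, so the 75 point to a structure of the samples that follows it. The real split alone was as large for Ehf IKO against Control TMX (126 genes, highest other 0, 1 of 35), against both controls (70, highest other 0, 1 of 100) and against their mean (270, highest other 1, 1 of 100). This is the lowest share each of these tests can give, and it argues against chance without excluding it. For camera lists against the mean, 2 of 100 splits were as large (17 lists, highest other 18), and all 17 calls were lost with an estimated correlation. A share this low was set beforehand as arguing against chance, but another split called more lists, so chance is not excluded. Nor is it excluded for Control OIL (19, highest other 19, 2 of 35), Control TMX (11, highest other 19, 10 of 35) or the controls (17, highest other 20, 2 of 35).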

How the results depend on the processing

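The covariates of stromal, proliferation and clock genes were chosen only after the result was seen. The fit without Ehf IKO replicate 2 was planned, as 1 of the 12 that leave out a library. Counts of genes are given for Ehf IKO against Control OIL (OIL), Control TMX (TMX), both (both) and their mean (mean), and for Control TMX against Control OIL (controls), and those left out stayed within 1.5 times the reported count. Values in powers of 10 are rounded to 2 digits. With no filter they were 724 (OIL), 500 (TMX), 441 (controls), 229 (both) and 831 (mean), and by DESeq2 in the same order 491, 281, 186, 1.4e+02 and 441. DESeq2 also called Ehf against Control OIL (-0.33, adjusted p = 0.0351). The replicate block gave 173 (OIL), 72 (TMX) and 148 (mean), and the compared groups alone 1.1e+02 (OIL). The animal-number block, added to the fit of the compared groups alone, gave 174 (OIL). A 2-fold minimum gave 128 (OIL), 70 (TMX), 42 (both) and 117 (mean). The stromal score gave 35 (OIL), 5 (controls), 31 (both) and 148 (mean), the proliferation score 438 (OIL), 6 (controls) and 413 (mean), and the clock score 491 (OIL) and 83 (TMX). The immune score gave 73 (TMX), the colon region score 223 (TMX) and 23 (controls) and the sex term 38 (controls). The controls count was 5 with a mean log2 CPM of at least 1 and 8 by limma-voom. Leaving out each library gave 104 to 711 (OIL), 50 to 162 (TMX), 3 to 67 (controls), 36 to 106 (both) and 108 to 522 (mean), in that order lowest without Ehf IKO replicate 1, Control TMX replicate 3, Control TMX replicate 2, Control TMX replicate 3 and Ehf IKO replicate 3, and highest without Ehf IKO replicate 4 each time. Without Ehf IKO replicate 2 they were, in that order, 130, 66, 5, 42 and 1.4e+02. The 2-fold minimum is a stricter rule, and the cause of the other moves was not tested. Fewer samples cannot account for the rises without Ehf IKO replicate 4.

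DESeq2 size factors in edgeR kept every called result of a named gene. Of these 1.4e+02 results (rounded to 2 digits), 50 were called in every fit without 1 library and 42 in every other alternative, and none of them changed direction in any alternative run. All camera calls were lost with an estimated correlation. Replicate numbers do not pair the libraries: 5 of 12 same-number pairs correlated above 0.1. In Control OIL and Ehf IKO the animal-number block is the same as sex. With 4 libraries per group, edgeR recovered 79% of 2-fold changes in simulated, independent genes with an average log2 CPM above 1. Recovery of single changes under 2-fold was not measured.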

Other observations

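None of the tests in this part was planned as a test of an explanation, and the neighbouring genes were chosen only after the result was seen.

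A few genes of metabolism changed in Ehf IKO against the mean of both controls. Slc27a2, a fatty acid transporter gene, rose by 1.06 ± 0.17, at 4.88 ± 0.932, 3.66 ± 0.404 and 8.84 ± 1.84 CPM in Control OIL, Control TMX and Ehf IKO (edgeR adjusted p = 0.00454, n = 4 each), while Ppargc1a fell by 0.68 ± 0.14. Ppargc1a was at 35.9 ± 2.51, 68.0 ± 18.0 and 30.7 ± 2.03 CPM, so Control TMX was the high group, and it did not pass against Control OIL (-0.22 ± 0.16, adjusted p = 0.660). Both Slc27a2 and Ppargc1a are of a list of 31 PPAR targets and genes of fatty acid oxidation, of which 1 rose and 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.0804, and adjusted p = 0.760 with an estimated correlation). Of 34 genes of xenobiotic metabolism, 24 were higher and 2 rose, the glutathione transferase genes Gstm1 (0.62 ± 0.14) and Gsta1 (0.94 ± 0.23), and 5 rose adjusted over the list alone (camera adjusted p = 0.0255, and adjusted p = 0.760 with an estimated correlation). Against Control TMX, 20 of the 34 were higher and none passed, over all genes or adjusted over the list alone (camera adjusted p = 0.602, and adjusted p = 0.976 with an estimated correlation). Ppargc1a lost its call without Ehf IKO replicate 1 or 3 (up to adjusted p = 0.0860), and Gstm1 and Gsta1 in 6 and 8 of the 12 fits that leave out 1 library (up to 0.0647 and 0.180). The stromal score ended the calls of Ppargc1a and Gsta1 (adjusted p = 0.0679 and 0.199), and the replicate block those of Gstm1 and Gsta1.

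Against Control OIL, 24 of 26 genes of glycolysis and hypoxia were higher and 2 rose, Higd1a (0.78 ± 0.18) and Ndrg1 (0.68 ± 0.16), and 6 rose adjusted over the list alone (camera adjusted p = 4.8e-05, and adjusted p = 0.384 with an estimated correlation). In Control TMX against Control OIL, 21 of the 26 were higher, none passed over all genes and 6 rose adjusted over the list alone (camera adjusted p = 3.0e-06, and adjusted p = 0.412 with an estimated correlation). Against Control TMX, 11 were higher and 15 lower in Ehf IKO, and none passed over all genes or adjusted over the list alone (camera adjusted p = 0.698, and adjusted p = 0.976 with an estimated correlation). Higd1a and Ndrg1 lost their calls in 6 and 9 of the 12 fits that leave out 1 library (up to adjusted p = 0.118 and 0.151). The stromal score (adjusted p = 0.672 and 0.636) and the colon region score (adjusted p = 0.104 and 0.123) ended both calls.

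Cd177 and Ceacam10, with some of the largest falls, lie next to each other on chromosome 7, at 24743983 to 24760311 and 24777206 to 24784657. Both were also lower in Control TMX than in Control OIL.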
